A study of Homo sapiens with 4 samples.

How the data were processed

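RNA from 4 untreated cell lines of colorectal cancer (SW480, SW620, HCT116 and Caco2, grouped by the cell line named in the labels, 1 array each) was hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays as biotin-labelled amplified RNA, per the labels' protocols. The labels' protocols give 2 different amounts of input RNA, so the amount is not stated here. The deposited values are log2 signals per probe set that the authors computed with RMA (robust multi-array average: background correction, quantile normalisation between arrays and a summary over the probes of a set) in Affymetrix Expression Console, per the submitters' processing notes and the file headers. No version of either is given in the sources used here, and it is not given whether the 4 arrays were normalised together or with further arrays. RMA compresses large differences and leaves probe sets without transcript at low positive values, so a difference that ends near 2 to 5 log2 units is a difference from the array's floor, and levels of different genes cannot be set against each other. The detection column of each file held the same call for every probe set and was not used. The series matrix values were equal to those of the per-sample files for every probe set (0 differences).

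Of the probe sets on each array, 43383 carried 1 gene symbol, 1663 several, 9567 none, and 62 were controls. Symbols were updated through the Entrez gene ID with a RefSeq gene table (GRCh38.p14, used for names alone): 42702 of the 1-symbol probe sets matched and 3236 symbols changed. Coordinates are the probe set alignments of the files, on GRCh37. Probe sets with several symbols or none were not assigned to genes, and 64 probe sets of XIST or the Y chromosome were left out. A gene's value was that of its probe set with the highest mean over the 4 arrays, among those with exactly 1 symbol. This gave 21261 genes, 11009 of them with 2 or more probe sets.

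Genes were counted by size, since 1 array per line allows no test. Between 2 lines a gene counted when the log2 difference was at least 2 and the brighter array at least 7. For a line alone, or for SW480 and SW620 together, the gap to the nearest of the lines compared had to be at least 2 and the lower edge of the brighter side at least 7. Named genes were taken from the 10 largest differences up and down by these rules for SW620 minus SW480, for each line alone and for the SW480 and SW620 pair, without genes known by a clone or LOC number alone, plus members of 24 gene lists. The rules, lists, comparisons and alternatives were fixed before the data were examined, except cyclic loess for the chromosome arms described below. The lists cover brush border, intestinal transcription factor, epithelial, mesenchymal, Wnt target, p53 target, mismatch repair, goblet, enteroendocrine, MHC class I, interferon-stimulated, proliferation, cholesterol, liver and fetal gut, hypoxia, drug transport, NRF2 target, cancer-testis, invasion, growth factor and reference genes, and markers of fibroblasts, leukocytes and endothelial cells. Members without a 1-symbol probe set were not measured. For each list the median log2 difference was placed among 10000 random lists of the same size drawn from the same 20 expression bins, and called below percentile 1 or above percentile 99. The 6 comparisons per list were each line minus the mean of the other 3, SW620 minus SW480, and the mean of SW480 and SW620 minus the mean of Caco2 and HCT116. With 24 lists and 6 comparisons, chance alone gives some calls, and the comparisons share arrays. In a list, a member was counted as up or down at a difference of at least 2 with the brighter side at least 7.

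Alternatives were the series matrix values, the median over all probe sets of a gene, probe sets without the suffixes _x_at, _s_at and _a_at (which mark probes shared between transcripts or genes), each array centred on the median of genes with a mean of at least 7, cyclic loess between the 4 arrays (limma 3.58.1, R 4.3.3, 3 iterations), a fold threshold of 2, a bright side of at least 8 or no minimum, and other sets of lines compared. Chromosome arm shifts used the same percentiles over autosomal arms with at least 20 genes with a mean of at least 7. Precision rests on the number of arrays and on within-array estimates. These were the SD between arrays of spiked-in control probe sets, and the spread of a log2 difference between bright probe sets of 1 gene. The size rule for pairs of lines and the list shifts were tested on simulated data, and the other steps were not. For SW620 minus SW480, 21261 genes were simulated with a noise SD of 0.25 and 200 changed genes, drawn from those with a mean of at least 8. The size rule recovered 46 of 50 genes with a true log2 difference of 2.5, 50 of 50 at 3 and 50 of 50 at 4, and called 0 of 50 at 1 and 0 of 21061 unchanged genes. For HCT116 minus Caco2, 5 of 200 simulated lists of 30 genes without a shift were called, and 200 of 200 with a shift of 0.5. Apart from these changes the simulated lines differed by noise alone. Recovery near the minimum of 7, and of lists among real differences between lines, was therefore not tested. With noise this small against a cut of 2, no false call was to be foreseen. The 0 calls among unchanged genes thus give no error rate for real arrays. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.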

Results

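Basal gene expression was measured in 4 human cell lines from colorectal tumours, SW480, SW620, HCT116 and Caco2, with 1 Affymetrix Human Genome U133 Plus 2.0 array per line. Caco2 is widely used as a model of the absorptive intestinal epithelium, HCT116 as a line with deficient DNA mismatch repair, and SW480 and SW620 as a primary tumour line and a metastasis line of common origin. The cells were untreated, so the comparisons ask how the resting transcriptomes of the lines differ. From each array 21261 genes were read, and 8716 of these (41.0%) had a mean log2 value of at least 7 over the 4 arrays. Because each line was represented by a single array, no difference below has a replicate check, and no p-value or standard error is given. The within-array estimates of error were a median SD between arrays of 0.14 log2 units over 18 hybridisation control probe sets, with a largest difference between any pair of arrays of 0.50. Over 24 poly-A controls, which also cover labelling, these were 0.21 and 0.74. The log2 difference between 2 lines had a pooled SD of 0.24 to 0.44 between probe sets of the same gene, depending on the pair. This covers the 3413 genes with 2 or more probe sets of a mean of at least 7, and no dimmer probe sets. The SW480 array read higher than the rest: the median of genes with a mean of at least 7 was 9.02 in SW480, 8.90 in HCT116, 8.75 in SW620 and 8.71 in Caco2, and the median gene differed by -0.25 log2 units between SW620 and SW480. List medians are therefore given beside the median of random gene lists matched on expression, which carries the same shift. A line that is high on a list also raises the mean that other lines are set against, and so lowers their values on that list. A line that is low on a list does the reverse.

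SW480 and SW620 were the most alike of the 6 pairs of lines, and Caco2 and HCT116 the least alike. Across the 8716 genes with a mean of at least 7, Pearson's r was 0.856 between SW480 and SW620 (Spearman's rho 0.859), 0.791 between SW480 and HCT116, 0.766 between SW480 and Caco2, 0.753 between SW620 and each of Caco2 and HCT116, and 0.725 between Caco2 and HCT116 (these correlations run across genes, which are not independent replicates). A gene was counted as apart when the log2 difference was at least 2 (4-fold) and the brighter array read at least 7. By that rule 556 genes were apart between SW620 and SW480, 113 higher and 443 lower in SW620. The other pairs had 858 genes (SW480 minus HCT116, 549 higher and 309 lower), 997 (SW620 minus HCT116, 386 and 611), 1037 (SW620 minus Caco2, 433 and 604), 1099 (SW480 minus Caco2, 709 and 390) and 1151 (HCT116 minus Caco2, 639 and 512). With each array centred on its own median, the split of SW480 minus Caco2 became 539 higher and 493 lower, so the share of higher genes moved from 64.5% to 52.2%. For HCT116 minus Caco2 the majority turned over, to 555 higher and 605 lower with centring and to 574 and 592 after cyclic loess. Among the 158 genes apart between SW620 and SW480 that had several bright probe sets, all 158 had every bright probe set on the same side, and for HCT116 minus Caco2 this held for 339 of 343 genes. Folds depend on the probe set chosen: with the median over all probe sets of a gene, 56 of the 118 largest differences named below moved by at least 0.36 log2 units, all keeping their sign.

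**Figure D1:**
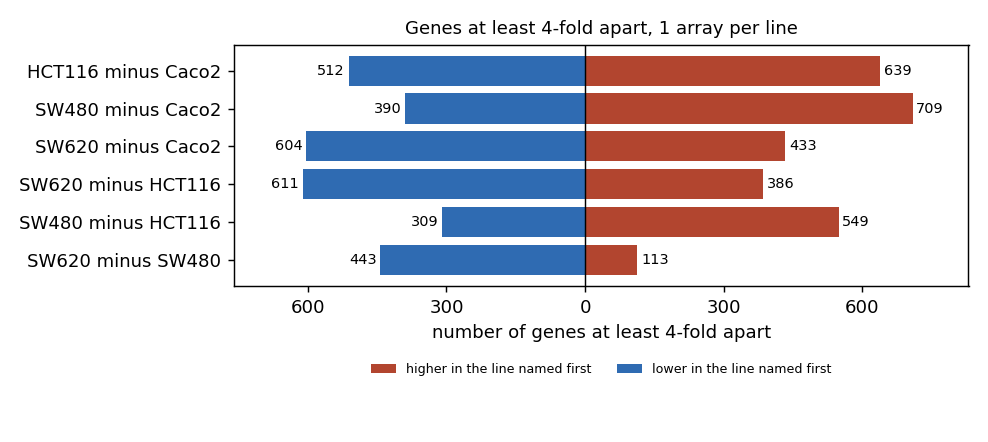
Number of genes at least 4-fold apart in each of the 6 pairs of lines (x axis, counts of genes; 1 array per line), with genes higher in the line named first to the right of 0 and lower genes to the left. SW620 minus SW480 has the fewest genes, 113 higher and 443 lower, and HCT116 minus Caco2 the most, 639 and 512 (555 and 605 with each array centred).

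The comparison of SW620 with SW480 sets the metastasis line against the primary tumour line of the same origin. The genes furthest apart, GNG11 and WNT5A, were bright in SW480 alone of the 4 lines. The G protein subunit gene GNG11 (chromosome 7, 93551358 to 93555821 on GRCh37) read 11.72 in SW480 and 2.09 in SW620, a 791-fold difference. WNT5A, which encodes a non-canonical Wnt ligand, read 11.57 and 2.49 (539-fold), and RUNX2, the osteogenic transcription factor, 10.97 and 2.72 (303-fold). HPGD, the enzyme that inactivates prostaglandins, was 205-fold lower in SW620, and PHLDB2, IQGAP2, PIP5K1B, the basal keratin gene KRT5, MUCL1 and the kinase gene DCLK1 were between 152-fold and 113-fold lower. In the other direction, the imprinted gene PEG10 (chromosome 7, 94285681 to 94299007) read 2.92 in SW480 and 10.53 in SW620 (196-fold), and PROM1, which encodes the surface protein CD133, read 3.02 and 9.89 (117-fold). The next genes on the SW620 side were CEP15, KRT40, TOX3, HLTF, CYTL1, SHISA9, CNN3 and C9orf152, from 69.2-fold to 35.6-fold, of which HLTF and CNN3 were low in SW480 alone. Several bright probe sets, all in the same direction, were present for PEG10, KRT40, TOX3, WNT5A, HPGD, PHLDB2 and DCLK1. The rest of these 20 genes, GNG11 among them, had only 1 bright probe set, so agreement could not be checked.

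Genes of invasion and matrix turnover were lower in SW620 than in SW480 as a group. The median over 41 measured members was -1.23 log2 units, against -0.26 for matched random lists (percentile 0 of 10000 random lists, a description of these arrays), with 9 members at least 4-fold lower, 2 at least 4-fold higher and 30 neither. The chemokine receptor gene CXCR4 read 9.96 in SW480 and 3.88 in SW620, the chemokine gene CXCL2 9.06 and 5.76, and the matrilysin gene MMP7 8.65 and 5.86. CD44, CXCL1, CXCL3, CXCL8 and ITGA3 were also at least 4-fold lower. The matrix glycoprotein gene TNC went the other way, 5.00 in SW480 and 9.89 in SW620, as did MACC1, 6.82 and 9.11. Growth factor receptors and ligands had a median of -1.05 against -0.25 (percentile 0; 3 of 36 members down, 1 up), with the epidermal growth factor receptor gene EGFR at 7.12 in SW480 and 3.39 in SW620, BMP2 at 7.25 and 3.61, TGFBR1 at 10.36 and 8.24, and FGFR4 higher in SW620 (7.42 and 9.46). MHC class I presentation genes also lay lower in SW620, at a median of -1.05 against -0.25 (percentile 0), although 1 of 18 members, the immunoproteasome gene PSMB9 (8.88 and 5.49), passed the 4-fold rule. HLA-B read 11.99 in SW480 and 10.53 in SW620, and HLA-E 9.66 and 8.07. The other 21 lists were not called in this comparison. Among those, the Wnt target and stem cell genes went both ways, with PROM1 and LGR5 (5.20 in SW480 and 9.68 in SW620) higher and APCDD1, DKK1, LEF1, CD44 and CCND1 lower. Epithelial junction genes had MAL2, CLDN7 and DSC2 lower in SW620, and mesenchymal genes had TPM2 higher and GNG11 and CDH11 lower.

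**Figure D2:**
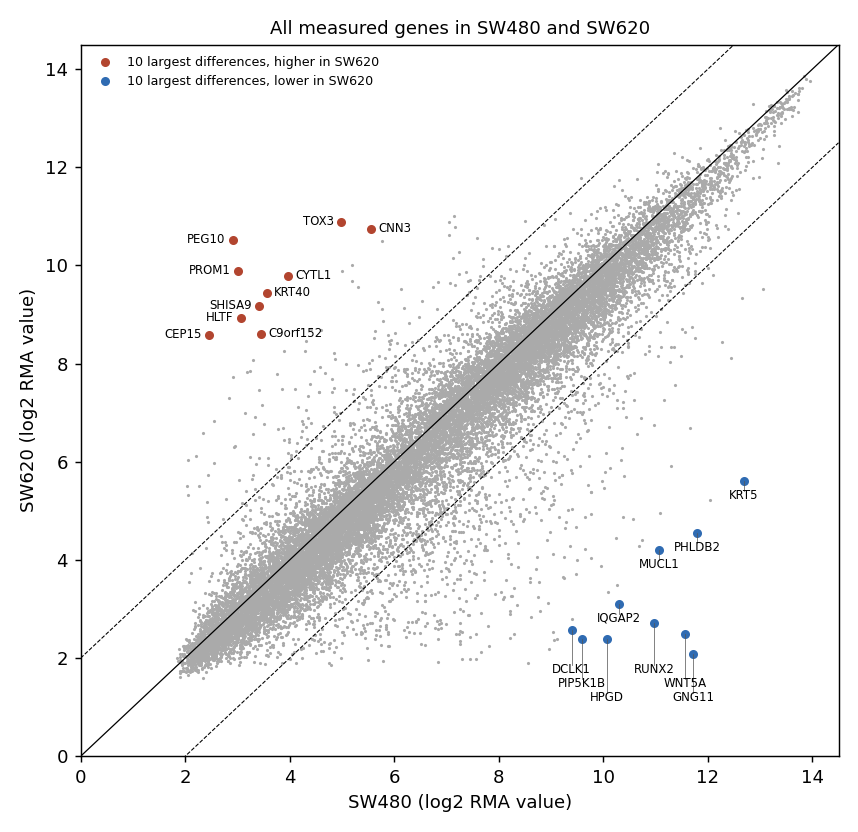
Log2 RMA value of each measured gene in SW480 (x axis) and SW620 (y axis), 1 array per line, with the line of equality, dashed lines at a 4-fold difference, and the 10 largest differences in each direction marked by gene. GNG11 and WNT5A lie at 11.72 and 11.57 in SW480 and at 2.09 and 2.49 in SW620, and more points lie below the lower dashed line than above the upper one.

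Caco2 stood apart most by genes of liver and fetal gut secreted proteins, with some enterocyte and some secretory genes also higher. By a rule that asks for at least a 4-fold gap to the nearest of the other 3 lines, 210 genes were high and 141 low in Caco2 alone. The apolipoprotein gene APOA2 (chromosome 1, 161192082 to 161193418) read 12.53 in Caco2, with a gap of 369-fold to the nearest other line. SPINK1, which encodes a secreted trypsin inhibitor, had a gap of 326-fold, the secretory disulphide isomerase gene AGR2 297-fold, the retinaldehyde dehydrogenase gene ALDH1A1 222-fold, the retinol carrier gene RBP4 216-fold, APOA1 162-fold and APOB 113-fold, followed by TFEC, UGT2A3 and PRSS35. Genes low in Caco2 alone were led by MSN, which encodes the membrane-cytoskeleton linker moesin (chromosome X, 64887615 to 64961792), at 2.88 in Caco2 against 10.80, 11.19 and 11.35 in HCT116, SW480 and SW620. The galectin gene LGALS1 read 4.93 in Caco2 and at least 11.88 elsewhere, the ETS factor gene ETV1 1.80 and at least 8.41, MCC 2.12 and at least 8.44, and the metalloproteinase inhibitor gene TIMP1 4.36 and at least 10.63. EPDR1, PPP2R2C, ANTXR1, PRR34-AS1 and AKAP12 completed the 10 largest losses, with gaps of 57.7-fold to 31.2-fold.

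Of 30 measured genes for liver and fetal gut secreted proteins, 18 were at least 4-fold higher in Caco2 than the mean of the other 3 lines and none was lower, with a median of 3.59 log2 units against -0.16 for matched random lists (percentile 100). Albumin (ALB) read 9.93 in Caco2 and at most 4.36 elsewhere, alpha-fetoprotein (AFP) 10.78 and at most 4.94, AHSG 11.30 and at most 5.29, and vitronectin (VTN) 10.27 and at most 4.20. Intestinal transcription factors had a median of 1.35 against -0.18 (percentile 100), and 5 of 22 were at least 4-fold higher: GATA6 (11.28 in Caco2; 8.10, 3.67 and 4.53 in HCT116, SW480 and SW620), FOXA1, HNF4A (11.37; 5.14, 8.56 and 9.19), ISX and CDX2. Brush border and enterocyte genes had a median of 1.14 against -0.14 (percentile 100), and 8 of 27 were up, among them CDH17 (11.40 and at most 5.68), the fatty acid binding protein gene FABP1 (9.37 and at most 4.48), the peptidase gene DPP4 (9.63 and at most 6.03) and KRT20 (7.31 and at most 5.89). The disaccharidase genes SI (5.10 in Caco2) and LCT (5.13) did not reach 7 in any line. Epithelial junction genes had a median of 1.02 against -0.14 (percentile 100; 6 of 32 up), with E-cadherin (CDH1) at 12.38 in Caco2 and 9.19, 8.19 and 8.23 elsewhere, and KRT7 down (3.96 in Caco2). Drug transport and detoxification genes (0.90 against -0.16, percentile 100; 7 of 36 up, 1 down) included the efflux pump gene ABCB1 at 9.24 in Caco2, 2.47 in HCT116, 8.12 in SW480 and 6.77 in SW620. That call ended when only members with a mean of at least 7 were used (median 0.25, percentile 97.8). Cholesterol synthesis genes lay higher together, at 0.80 against -0.15 (percentile 100), with none of 23 members past the 4-fold rule and IDI1 at 11.20 in Caco2 against 10.05, 9.16 and 9.34. Goblet and secretory genes were higher (0.65 against -0.16, percentile 100; 5 of 23 up), through AGR2, the trefoil factor genes TFF1 (10.37 and at most 4.47), TFF2 and TFF3, and SYTL2, whereas the mucin gene MUC2 read 4.97. Invasion and matrix genes were called high at 0.13 against -0.15 (percentile 99.5; 6 of 41 up, 2 down), with MMP1 at 8.23 and at most 3.36, and lost that call after cyclic loess (percentile 98.8).

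Mesenchymal genes were lower in Caco2, with a median of -0.97 against -0.14 (percentile 0) and 10 of 27 at least 4-fold lower. Vimentin (VIM) read 6.42 in Caco2, 8.47 in HCT116, 11.63 in SW480 and 11.89 in SW620, and the repressor gene ZEB1 2.25, 6.32, 7.53 and 7.79. TCF4, TGFBI and fibronectin (FN1, 12.88 in Caco2) were higher, and the call ended with only probe sets that carry no _x_at, _s_at or _a_at suffix (median -0.32, percentile 6.38). Interferon-stimulated genes were also lower, at -1.04 against -0.17 (percentile 0; 5 of 33 down), with IFITM3 at 6.01 in Caco2 and at least 9.57 elsewhere. HCT116, where this list was high, is part of the mean in this and the other low calls of the list.

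HCT116 stood apart by interferon-stimulated genes. In HCT116 alone 153 genes were high and 108 low. The cancer-testis antigen genes MAGEA6 (chromosome X, 151869113 to 151870809) and MAGEA3 read 10.95 and 10.94, with gaps of 205-fold and 190-fold. They are near-identical copies, so their signals cannot be separated on this array. GTSF1, a germline factor gene, had a gap of 167-fold and MIR100HG, the host transcript of miR-100, 115-fold, followed by ZNF518B, LRRTM4, LINC00326, IFIT1, RAB34 and SLC27A6 at 107-fold to 42.1-fold. The polyubiquitin gene UBB (chromosome 17, 16284410 to 16286054) read 4.25 in HCT116 and 13.12, 13.45 and 13.21 in Caco2, SW480 and SW620, a gap of 469-fold. The forkhead gene FOXQ1 was 177-fold lower. The mitochondrial transhydrogenase gene NNT and its antisense transcript NNT-AS1 were 86.1-fold and 73.3-fold lower. TM4SF1, SORBS2, AGMAT, SPAG16, PROX1 and ASCL2 were 56.3-fold to 39.5-fold lower.

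Of 33 interferon-stimulated genes, 19 were at least 4-fold higher in HCT116 than the mean of the other 3 lines and none was lower (median 2.08 against 0.10, percentile 100). IFIT1 read 10.63 in HCT116 and at most 4.93 elsewhere, IFI6 12.16 and at most 7.96, IFI44 7.33 and at most 2.92, and ISG15 12.15 and at most 9.67. MX1 did not share the shift (5.18 in HCT116 and 6.70 in SW480). p53 target genes had a median of 0.96 against 0.11 (percentile 100), and TP53INP1, the cell cycle inhibitor gene CDKN1A (10.50 in HCT116; 7.87, 9.41 and 5.78 in Caco2, SW480 and SW620), GDF15, FAS and PLK2 made up the 5 of 30 at least 4-fold higher, with none lower. Hypoxia and glycolysis genes had a median of 0.84 against 0.08 (percentile 100; 3 of 26 up, 1 down), with NDRG1 at 10.65 and at most 8.71 elsewhere, BNIP3 and ALDOC higher and the glucose transporter gene SLC2A3 lower (6.16 in HCT116). BNIP3 was bright in Caco2 too (10.59 in HCT116 and 9.55 in Caco2) and low in SW480 and SW620 (2.74 and 3.58). Cancer-testis antigen genes were not called as a list (percentile 7.57), yet MAGEA12, MAGEB2, PRAME and the joint signal of MAGEA3 and MAGEA6 were at least 4-fold higher.

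Wnt target and stem cell genes were lower in HCT116, at a median of -0.44 against 0.06 (percentile 0), with 10 of 29 at least 4-fold lower and 1, DKK1, higher. The intestinal stem cell receptor gene LGR5 read 1.90 in HCT116, 9.82 in Caco2, 5.20 in SW480 and 9.68 in SW620, and PROX1, ASCL2, APCDD1, PROM1, LEF1 and NKD1 were also lower, whereas MYC read 11.13 in HCT116 and 10.89 to 11.33 elsewhere. Intestinal transcription factors (-0.55 against 0.11, percentile 0.01; FOXA2 and HNF4A down) and liver secreted protein genes (-0.94 against 0.10, percentile 0; 2 of 30 down, 1 up) were lower too, as were brush border genes (-0.51 against 0.09, percentile 0; 4 of 27 down, with villin, VIL1, at 4.64 and at least 9.05 elsewhere). Caco2, high on all 3 of these lists, is part of the mean, which lowers these values. The brush border call ended with only probe sets that carry no suffix (percentile 7.96). DNA mismatch repair genes were not called as a list (percentile 11.7), but MSH3 read 5.73 in HCT116 and at least 7.91 elsewhere.

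In SW480 alone 129 genes were high and 8 low. The largest gaps were those of GNG11 (735-fold) and WNT5A (310-fold), followed by KRT5 (12.68 and at most 5.61 elsewhere), NELL2, the growth factor carrier gene IGFBP3, MUCL1, the monocyte chemokine gene CCL2 (9.49 and at most 4.01), the decoy receptor gene TNFRSF11B, CST1 and FGF20 (39.8-fold). The 8 low genes were HLTF (chromosome 3, 148747850 to 148804341), a chromatin remodelling helicase gene that read 3.06 in SW480 and at least 8.93 elsewhere, CNN3, the aldose reductase gene AKR1B1, SGCE, AQP3, PRRT3-AS1, PLCB1 and PLOD2, with gaps of 58.6-fold to 6.10-fold. When SW620 was left out of the lines compared, 264 genes were high and 81 low. Against the mean of the other 3 lines, mesenchymal genes had a median of 0.90 against 0.18 (percentile 100; 8 of 27 up, 1 down), with AXL at 10.15 in SW480 and 5.38, 8.21 and 8.65 in Caco2, HCT116 and SW620. Wnt targets had 0.83 against 0.20 (percentile 100; 5 of 29 up, 1 down), with the feedback gene AXIN2 at 12.01 against 8.51, 8.79 and 10.89. Caco2 was low on the mesenchymal list and HCT116 on the Wnt target list, which raises these values. Invasion and matrix genes had 0.71 against 0.20 (percentile 100; 5 of 41 up), growth factor genes 0.57 against 0.22 (percentile 99.97; 7 of 36 up, 3 down) and MHC class I genes 0.67 against 0.20 (percentile 99.9; 3 of 18 up). These last 3 calls ended with only probe sets that carry no suffix (percentiles 94.6, 96.8 and 98.9), and the growth factor call also with members of a mean of at least 7 (percentile 91.6). Liver secreted protein genes were lower (-1.05 against 0.20, percentile 0) than a mean that includes Caco2, where this list was high. Brush border, epithelial, interferon-stimulated, drug transport and NRF2 target genes were called low with medians of -0.27, -0.07, -0.09, -0.07 and -0.05, against 0.18 to 0.22 for random lists, and each of these 5 calls ended under at least 1 alternative. Caco2 was high on the brush border, epithelial and drug transport lists and HCT116 on the interferon-stimulated list.

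In SW620 alone 47 genes were high and 70 low, and with SW480 left out of the lines compared 168 and 179. The hair keratin gene KRT40 (chromosome 17, 39133967 to 39140530) read 9.45 in SW620 and at most 3.56 elsewhere (59.4-fold), and CYTL1, SHISA9, CEP15, C9orf152, TNC, the calcium-binding protein gene CALB1, AMIGO2, the proteoglycan gene LUM and ADAMTS18 followed, down to 17.9-fold. The low genes were led by MAL2 (chromosome 8, 120220629 to 120257911), which encodes a protein of apical transport in polarised epithelia, at 2.40 in SW620 and at least 9.11 elsewhere (105-fold). DIPK2A, GULP1, PTPRG, PTGR1, PDGFC, the tight junction gene CLDN7 (4.88 and at least 9.95), the Wnt receptor gene FZD7, MTUS1 and RAPGEF5 were 55.3-fold to 27.4-fold lower. Epithelial junction genes were lower as a list (-0.57 against -0.14, percentile 0.01; 6 of 32 down, 1 up), a call that ended with members of a mean of at least 7 (percentile 3.34). Invasion and matrix genes (-0.89 against -0.14, percentile 0; 4 of 41 down, 3 up), interferon-stimulated genes (0.85 log2 units below random lists, percentile 0; 3 of 33 down) and p53 targets (-0.59 against -0.13, percentile 0; 3 of 30 down) were lower, with HERC5 at 2.69 in SW620 and at least 6.53 elsewhere, and CDKN1A at 5.78 and at least 7.87. Wnt targets were higher (0.30 against -0.13, percentile 100; 8 of 29 up, 2 down), led by PROM1, LGR5, NKD1 (11.11 in SW620 and 9.88 in SW480, the nearest line), PROX1 and NOTUM. The mean here includes HCT116, low on the Wnt target list, which raises this value. PROM1 read higher in Caco2 (10.79) than in SW620 (9.89), and LGR5 slightly higher, so neither was particular to SW620. Brush border (-0.68), liver (-1.22), goblet (-0.61), drug transport (-0.73), cholesterol (-0.48), hypoxia (-0.49) and MHC class I (-0.47) lists were also called low, against -0.19 to -0.12 for random lists. The mean includes Caco2, high on the first 5 of these and on epithelial genes, and HCT116, high on hypoxia, p53 target and interferon-stimulated genes, while against SW480 alone only the MHC class I list of these 7 was called. With only suffix-free probe sets the p53, drug transport, cholesterol, hypoxia and MHC class I calls ended, and the goblet call ended with members of a mean of at least 7.

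**Figure D3:**
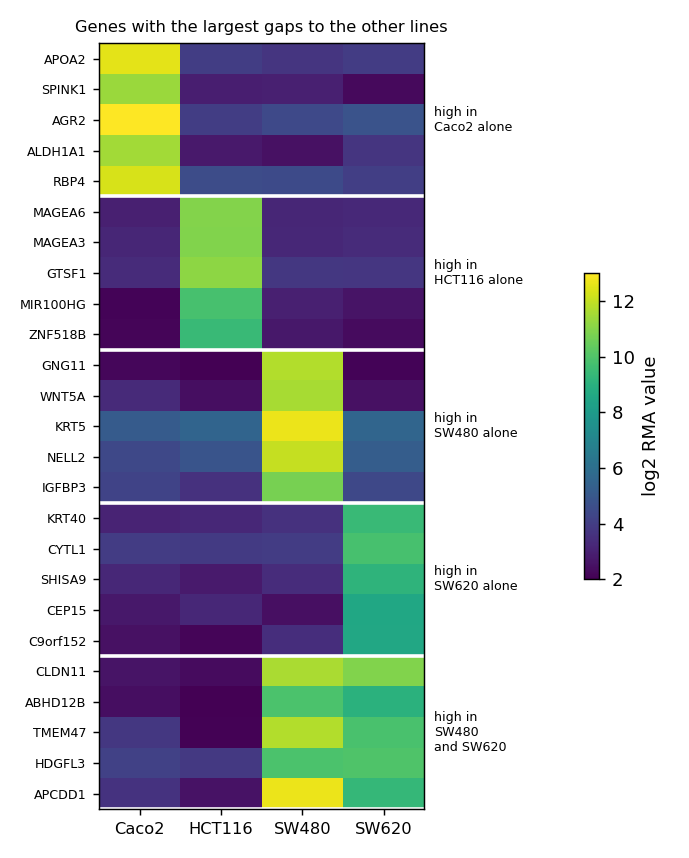
Log2 RMA values (colour, from 2 to 13) of the 5 genes with the largest gap above the other lines, for each line alone and for SW480 and SW620 together (rows, genes; columns, the 4 lines with 1 array each). APOA2 reads 12.53 in Caco2 and GNG11 11.72 in SW480, and the bottom block is bright in both SW480 and SW620, as for CLDN11 at 11.59 and 10.91.

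SW480 and SW620 together differed from Caco2 and HCT116 by 74 genes high and 61 genes low in both. The tight junction gene CLDN11 (chromosome 3, 170151052 to 170152037) read 11.59 in SW480 and 10.91 in SW620, against 2.59 in Caco2 and 2.31 in HCT116, a gap of 321-fold. ABHD12B, TMEM47, HDGFL3, the Wnt-responsive gene APCDD1, the forkhead gene FOXL2, LRRC34, the tyrosine kinase gene SYK and ZNF506 had gaps of 99.7-fold to 32.5-fold. Among the genes low in both, HS6ST2, a heparan sulfate sulfotransferase gene (chromosome X, 131760043 to 132092021), had a gap of 183-fold, the inflammasome gene NLRP2 72.0-fold, the mitophagy gene BNIP3 62.7-fold, the cytokine gene IL18 45.3-fold and the epithelial trafficking gene RAB25 38.9-fold. NECTIN3, FAM13A, LNCAROD, RTL8A and the EGFR ligand gene AREG (6.26 and 4.83 in SW480 and SW620, 11.12 and 11.91 in Caco2 and HCT116) followed. Epithelial junction genes were lower in the pair (-0.54 against 0.05, percentile 0; 8 of 32 down, 1 up), including the epithelial regulator gene GRHL2 (3.47 and 3.19, against 7.91 and 7.50), PRSS8 and CDH1, and KRT7 was higher (8.59 and 8.57, against 3.96 and 5.70). EPCAM was bright in all 4 lines, from 12.28 to 12.76. Mesenchymal genes were higher (0.97 log2 units above random lists, percentile 100; 6 of 27 up), a call that ended with only suffix-free probe sets (percentile 97.2), and CDH2, TWIST1 and POSTN stayed below 5 in every line. Caco2, low on the mesenchymal list, is part of the mean compared, and SW620 was not called on it against the mean of the other 3 lines (percentile 24.9). Wnt targets were higher (0.60 against 0.05, percentile 100; 7 of 29 up, 1 down), with NOTUM at 10.03 and 11.20, against 6.38 and 7.07. HCT116, low on the Wnt target list, is part of the mean compared, which raises this value. Liver secreted protein genes (-1.69, 9 of 30 down), interferon-stimulated genes (-0.82, 1 of 33 up and 1 down, with HCT116 in the mean), brush border genes (-0.71) and goblet genes (-0.46) were lower, against 0.01 to 0.05 for random lists and all at or below percentile 0.05, as were cholesterol, drug transport, hypoxia, p53 target, NRF2 target and intestinal transcription factor lists with medians from -0.50 to -0.27, against 0.04 to 0.06. Caco2 was itself high on the liver, brush border, goblet, cholesterol, drug transport and intestinal transcription factor lists, and HCT116 on the hypoxia and p53 target lists. The goblet and intestinal transcription factor calls ended with members of a mean of at least 7, and the cholesterol, drug transport, hypoxia, p53 target and NRF2 target calls with only suffix-free probe sets.

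Proliferation genes and reference genes were not called in any of the 6 comparisons, and none of their members passed the 4-fold rule. MKI67 lay between 9.52 and 10.11 and TOP2A between 10.56 and 11.75, and ACTB between 13.45 and 13.72. Enteroendocrine and neuronal genes were not called either, although SCG2 (8.31 in HCT116), PAX6 (8.48 in SW480), CHGB (7.55 in SW620) and UCHL1 (8.60 in Caco2) were each at least 4-fold higher in 1 line than the mean of the other 3. NRF2 target genes were not called in Caco2, HCT116 or SW620. Markers of other cell types, fibroblasts, leukocytes and endothelial cells, were not called in any comparison. Single members were bright: the lysozyme gene LYZ read 11.18 in Caco2, LUM 8.70 in SW620 and LAPTM5 8.52 in SW480, while the pan-leukocyte gene PTPRC read at most 3.31, the endothelial gene CDH5 at most 3.12 and COL3A1 at most 3.76.

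**Figure D4:**
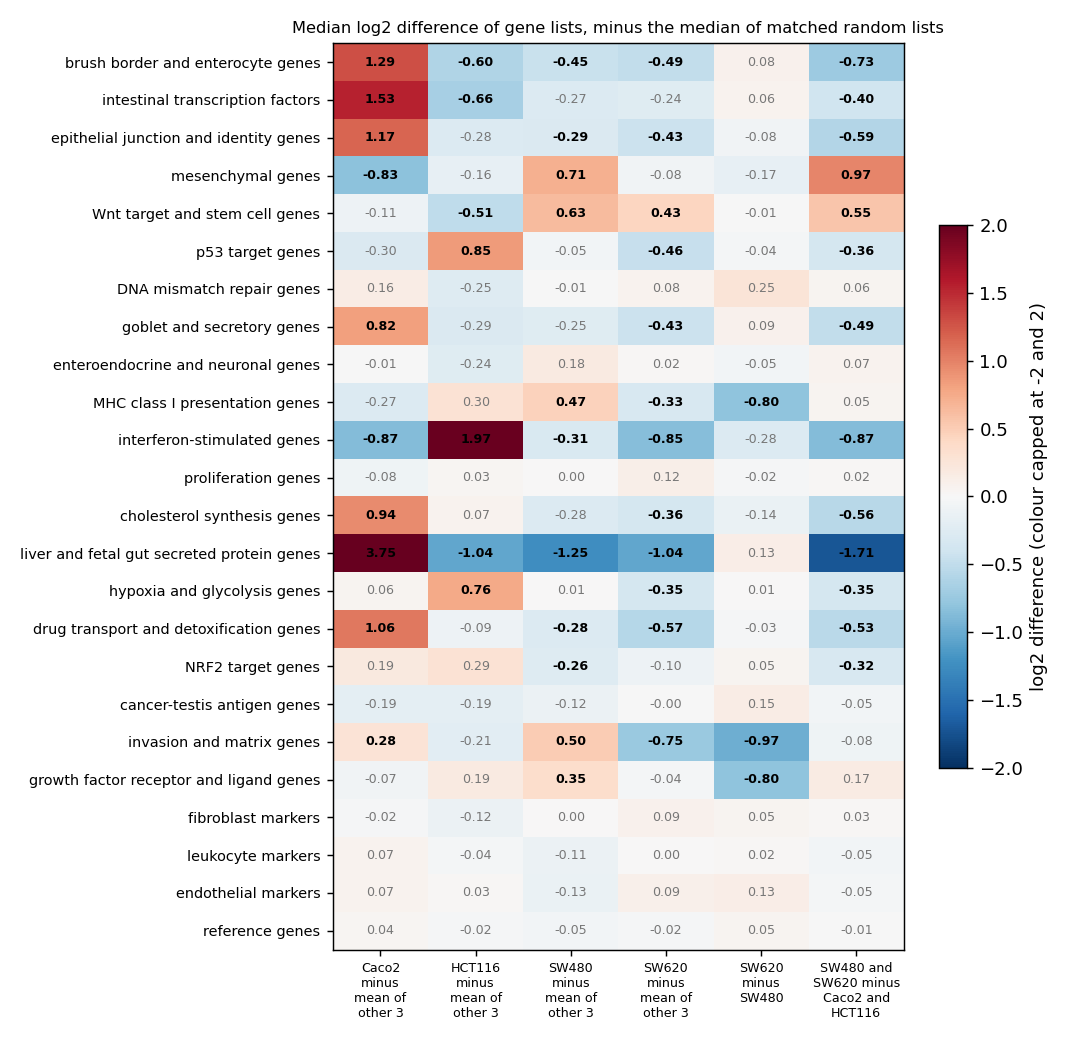
Median log2 difference of each of the 24 gene lists (rows) in each of the 6 comparisons (columns), minus the median of 10000 random lists matched on expression; bold values lie below percentile 1 or above percentile 99, and each line is 1 array. The liver and fetal gut list in Caco2 (3.75) and the interferon-stimulated list in HCT116 (1.97) stand highest, and proliferation, reference and other cell type lists have no bold value.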

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

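All alternatives here were fixed before the data were examined, except cyclic loess for the chromosome arms. The series matrix values equalled the main ones, so that alternative tests nothing. Centring each array and cyclic loess left all 16 gene counts within 1.5 times. Of 56 list calls, 55 held with centring, 55 with cyclic loess, 50 with the median over probe sets and 38 with suffix-free probe sets, and of 51 lists with enough members of a mean of at least 7, 38 calls held. All 118 named gene differences kept their sign under every alternative that gave a value, but 56 moved by at least 0.36 log2 units with the median over probe sets and 18 with suffix-free probe sets. One list reversed relative to random lists: goblet and secretory genes in SW620 had a median of -0.0548 with members of a mean of at least 7. The cause of the moves below was not tested where the alternative is not itself a looser or stricter rule.

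With a fold threshold of 2 the pair counts were 1777 (SW620 minus SW480), 2892 (HCT116 minus Caco2), 2838 (SW480 minus Caco2), 2472 (SW620 minus Caco2), 2337 (SW480 minus HCT116) and 2484 (SW620 minus HCT116). Genes high and low in 1 line became 450 and 456 (Caco2), 503 and 252 (HCT116), 433 and 36 (SW480), 155 and 233 (SW620), and 218 and 138 for the SW480 and SW620 pair. With a bright side of at least 8 the counts that moved were 564 (SW480 minus HCT116), 634 (SW620 minus HCT116), and genes low in Caco2 80, HCT116 43, SW480 5, SW620 42 and the pair 40. With no minimum, 870 (SW620 minus SW480), 1727 (HCT116 minus Caco2), 1523 (SW620 minus HCT116), genes low in Caco2 248, HCT116 207, SW480 18, SW620 148, the pair 96, and genes high in the pair 124. With the median over probe sets, genes low in Caco2 were 84, in HCT116 66, in SW620 36 and in the pair 38. With the sister line left out of the lines compared, SW480 had 264 high and 81 low genes and SW620 168 and 179. Over all genes, Pearson's r was 0.947 (SW620 and SW480), 0.891 (HCT116 and Caco2), 0.905 (SW480 and Caco2), 0.903 (SW620 and Caco2), 0.916 (SW480 and HCT116) and 0.904 (SW620 and HCT116). Signal over background limits the low side: a gene that is dark in a line has a floor value, so its fold is set by the bright line.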

Other observations

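The tests of the SW480 array's level, the test of the parts of the arms, cyclic loess for the arms, the level test for the zinc finger genes, the genes of the 7q segment and SMAD4 were chosen after their values had been seen. The other tests were set out before their results were known, although the zinc finger pattern itself was noticed in the gene lists.

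The median expression of chromosome arms differed between the lines. Of 39 autosomal arms in 6 comparisons, 158 of 234 arm medians (67.5%) lay outside percentiles 1 to 99 of random lists. The largest shift was 16q in SW620 minus SW480, where the median of 199 genes was 0.52 log2 units against -0.25 for random lists and 82.4% of the genes lay on that side. Against the mean of the other lines, HCT116 was high on 18q (0.77 against 0.10, 84 genes) and 8q (0.65 against 0.08, 188 genes). It was low on 20q (-0.53 against 0.08, 176 genes). By the same measure, Caco2 was high on 20q (0.47 against -0.13) and 10p (0.36 against -0.15) and low on 17p (-0.62 against -0.15). SW480 was high on 7q (0.68 against 0.21) and 7p (0.62 against 0.21). A line that is high or low on an arm also moves the mean the other lines are set against. On 20q, the high Caco2 value lowers that of HCT116, and the low HCT116 value raises that of Caco2. On 18q all other lines were called low (Caco2 -0.41 against -0.17, SW480 0.03 against 0.22, SW620 -0.38 against -0.12), with HCT116 in each mean. These values alone do not show which line carries a shift. SW620 was low against SW480 on 19q (-0.62 against -0.25), with 84.8% of 237 genes on that side. Both parts of the arm, split at the median gene position, lay beyond the 90th or below the 10th percentile on the side of the shift in 115 of the 158, and on 7q in SW620 minus SW480 the shift lay in the first part (-0.66 relative to random lists, against -0.01). On 4 called arm shifts the first and second parts lay outside percentiles 1 to 99 on opposite sides. On 13q in SW620 minus SW480 the 79 genes nearer the centromere lay at -1.06 and the 79 further ones at 0.22 relative to random lists, and on 17q the parts lay at -0.27 and 0.18.

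The random lists are matched on expression, so they already carry most of any level or intensity-dependent difference between arrays. Cyclic loess removes the same kind of difference and could therefore change little. After it, 95.6% of the called shifts (151 of 158) were called on the same side, which adds no support. The median share of genes on the side of the shift, 67.0%, decides nothing about a few strongly different genes, because the call on the median fixes it. Over all 234 arm medians, called or not, the first part lay beyond the 90th or below the 10th percentile in 178. The second part did so on the same side in 65.7% of these (117) and on the opposite side in 12.9% (23). The 10% each expected for independent parts holds only where parts behave like random lists. With 178 of 234 first parts beyond these limits they did not, so 10% is too low a yardstick. Same-side parts still outnumbered opposite ones, as a difference that spans the arm, such as copy number, would give. The comparisons share arrays, no DNA was measured, and regional regulation stays open.

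The SW480 array read 0.23 log2 units above the mean of the other arrays at the median of genes with a mean of at least 7. The 18 hybridisation control probe sets, added in equal amounts, read higher on it by 0.22, as a level difference carried by the array would give. These controls join RNA that is already labelled, so they cannot show how much transcript the cells held. More transcript of most genes in SW480 therefore stays open. The poly-A controls, by design added before labelling, read only 0.06 above the other arrays, so a difference in RNA input or labelling is not separated from one of the hybridisation. The excess of genes lower in SW620 than in SW480 was smaller with centring (347 of 491) but did not even out. Part of it may therefore be array level, and the rest stays open between a difference of the cells and one that centring does not remove.

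Among the 108 genes low in HCT116 alone were 7 numbered zinc finger genes, where their share of the genes that read at least 7 in the other 3 lines gives 1.74. The class was picked because it was noticed there, so this count is no test. In Caco2 alone 4 such genes were low, in SW480 and SW620 0, and 4 were high in HCT116 alone. ZNF567, ZNF529, ZNF614, ZNF266, ZNF260 and ZNF573 lie on chromosome 19 and ZNF140 on chromosome 12, and ZNF567 read 2.04 in HCT116 and at least 7.17 elsewhere. Over all 482 such genes the median was -0.02 in HCT116 against 0.08 for random lists (percentile 0.06), with percentiles of 41.2 in Caco2, 98.2 in SW480 and 98.7 in SW620; this class, too, was picked from HCT116.

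Loss of the whole bands that hold the chromosome 19 genes is an unlikely source. In those bands 78 other genes with a mean of at least 7 had a median of 0.21 in HCT116 minus the mean of the other lines (quartiles 0.01 and 0.56). Of these, 0 were at least 4-fold lower. The mean includes HCT116, so a gene lost there and only moderately bright elsewhere is left out, and the count of 0 does not cover it. Over all 7429 genes that read at least 7 in the other 3 lines, cyclic loess changed HCT116 minus the mean of the other lines by at most 0.0634. On arrays already normalised a large change was hardly possible, so this was no real test. It shows only that the smooth level difference that cyclic loess removes was small beside these gaps. Signal shared between similar transcripts stays open: 100.0% of the 7 genes were lower on suffix-free probe sets, but these were the probe sets used from the start. Silencing, and deletion of single genes or of segments shorter than a band, stay open too, since neither DNA nor methylation was measured.

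Neighbouring genes on 7q went opposite ways in SW480. SGCE (94214541 to 94285478 on GRCh37) and the adjacent imprinted gene PEG10 (94285681 to 94299007) read 3.89 and 2.92 in SW480, against 8.25 and 10.53 in SW620, while CASD1 on one side (94164674 to 94186279) read 8.93 and 7.74 and PPP1R9A on the other 9.43 and 7.07. GNG11 and ASB4, in the same segment, read 11.72 and 10.71 in SW480 and 2.09 and 6.88 in SW620. SMAD4 on chromosome 18 read 3.66 in SW480 and 2.89 in SW620, against 7.96 in Caco2 and 9.28 in HCT116.

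Probe sets outside the gene table also differed. Of 9567 probe sets without a gene symbol, 121 were at least 4-fold higher and 13 lower in SW620 than in HCT116, 24 were higher and 9 lower in SW620 than in SW480, and 17 were higher and 41 lower in HCT116 than in Caco2. Of 1663 probe sets with several symbols, 2 were higher and 28 lower in SW620 than in SW480.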
